A study of Mus musculus with 41 samples.

How the data were processed

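RNA was measured in microglia sorted from the mouse cerebellum as cells positive for CD11b and Tmem119, amplified with SMART-seq v4 chemistry and sequenced as paired reads. The 41 libraries fall into 10 groups: wild-type (WT) and Niemann-Pick type C (NPC) mice at 1, 3, 6 and 9 weeks of age, NPC mice at 9 weeks given PLX5622, and their NPC 9w control group. Groups hold 4 libraries each, except 3 for NPC at 9 weeks and 5 each for PLX5622 and control, and the labels count mice as the replicates.

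The deposited table holds normalized counts, a signal per gene and library that the authors made by dividing gene counts by 1 size factor per library. Per the submitters' processing notes, the tools were FastQC 0.11.4, STAR 2.5.1b and DESeq2 with mouse build mm9, and the notes give neither the gene annotation nor the counting tool. Every value of a library was a whole multiple of 1 step within a tolerance of 1e-06, which was used to recover whole reads for count-based tests. Columns not used: 0. The table names 24015 genes by symbol, 5501 of them at 0 in all libraries. Of the symbols, 22709 were found in a GENCODE table and 22508 in a RefSeq table. Recovered reads ranged from 23.2 M to 40.5 M (M, 1e+06 reads) per library, and reads without molecular identifiers are not independent molecules, so depth bounds counting error only.

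Values were analysed as log2(value + 1) with R 4.3.3 and limma 3.58.1 (linear fit, moderated test with trend and robust options, two-sided), keeping genes with at least 10 normalized counts in at least 3 libraries of the fit. Adjusted p-values are Benjamini-Hochberg values over the genes tested, with a threshold of 0.05. The comparisons of age and genotype used 1 fit of 31 libraries with 14046 genes and 23 residual degrees of freedom. The comparison of PLX5622 with control used its 10 libraries, 12877 genes and 8 residual degrees of freedom. The comparison of control with untreated NPC mice used all 41 libraries, 14312 genes and 31 residual degrees of freedom. Fold changes carry 95% confidence intervals, and ± gives an SD for group means and a standard error (SE) for log2 changes. Where 2 groups are compared, a higher value is in the group named first.

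A total of 21 gene lists were fixed by name: homeostatic microglia (23 genes), disease-associated microglia (40), lysosome (49), cholesterol biosynthesis and uptake (25), LXR targets and lipid storage (22), interferon response (38), cell cycle (34), inflammatory cytokines and NF-kB (28), antigen presentation (19), complement and Fc receptors (16), immediate early and stress genes (27), glycolysis (19), oxidative phosphorylation (35), and markers of neurons (16), oligodendrocytes and myelin (14), astrocytes and Bergmann glia (13), endothelial cells and pericytes (14), border-associated macrophages (12), monocytes and neutrophils (16), lymphocytes (16) and erythrocytes (10). Some genes belong to more than 1 list, and Lilrb4a, Ifit3b and Ighm were not in the table. Lists were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists within each comparison. The gene lists, the tests, the alternatives named in advance and the rule for named genes were set before the data were examined.

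Genes are named by this rule. Each comparison names up to 8 genes with the largest rise and 8 with the largest fall among genes past the threshold with a mean of at least 100 normalized counts in the higher group, an official symbol and no overlap between the groups' libraries. From each list it adds the 2 members with the smallest adjusted p, and for NPC against WT the 2 with the smallest adjusted p at 9 weeks. The interaction and the control comparison take 4 and 4. Npc1, Tmem119, Itgam and Csf1r may be named in every comparison, and the text names a part of the genes this allows.

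Library letters were checked for pairing by correlating the residuals of WT and NPC libraries with the same letter. At 1 week all 4 pairs correlated above 0.1 (r from 0.111 to 0.163) and each library matched best with its own letter, so results at 1 week are also given with a replicate block where that ends a call.

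Alternatives covered the pseudocount, the filter, rescaling to the same total, quantile normalization, array weights, a replicate block, the libraries in the fit, edgeR 4.0.16 and DESeq2 1.42.0 on recovered reads, and leaving out each library in turn. Further alternatives were added after seeing the data: covariates for the astrocyte score, the immediate early gene score, Xist and the monocyte and neutrophil score, fits without NPC 3w replicate C or without both NPC 6w replicates B and C, and repeats of the list and overlap tests without single libraries or with a replicate block, and a replicate block by letter for WT 9 weeks against 1 week. The procedure was tested on simulated data, drawn as negative binomial reads with the depths and dispersions of the real libraries. At a simulated fold of 2 it recovered between 19.4% (interaction) and 55.2% (WT 9 weeks against 1 week) of the changed genes, and at 4 between 59.1% (NPC against WT at 9 weeks) and 80.3% (PLX5622 against control), and it called between 3 and 8 unchanged genes. Differences of under 2-fold were therefore often missed in the simulation. It changed only a small part of the genes, so its rates do not carry over directly to comparisons with many changes. The median absolute log2 change of genes called in NPC against WT was between 0.80 (1 week) and 0.95 (9 weeks).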

Results

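Gene expression was measured in microglia, the resident macrophages of the brain, taken from the cerebellum of BALB/c mice. Niemann-Pick type C disease (NPC) is a lysosomal storage disorder in which loss of the cholesterol transporter Npc1 leaves cholesterol in lysosomes. Wild-type (WT) and NPC mice were sampled at 1, 3, 6 and 9 weeks of age with 4 libraries per group, or 3 for NPC at 9 weeks. In a separate arm, 5 NPC mice given PLX5622, an inhibitor of the kinase Csf1r on which microglia depend, were set against 5 NPC control mice at 9 weeks. The 41 libraries held 23.2 M to 40.5 M recovered reads (M, 1e+06 reads; median 30.5 M). Between 12003 and 14485 genes had 3 or more reads in a library, and the 10 most abundant genes took 12.2% to 20.2% of the reads. The labels count mice as replicates, so the p-values measure the spread between mice, pooled over all groups of a fit. This takes the spread as equal between those groups. Unless stated, the libraries of the groups compared did not overlap for a gene described as having risen or fallen.

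Npc1, the mutated gene, separated the genotypes in every library. WT libraries lay between 2606 and 7386 normalized counts and NPC libraries of the time course between 291 and 785. The means were 3293 ± 521 in WT and 454 ± 96.6 in NPC at 1 week, and 5808 ± 920 against 629 ± 181 at 9 weeks (SD, n = 4, with n = 3 for NPC at 9 weeks). NPC libraries therefore fell by 2.87, 3.62, 3.59 and 3.24 on the log2 scale at 1, 3, 6 and 9 weeks (limma adjusted p between 1.75e-11 and 1.34e-08). PLX5622 and control libraries held 514 ± 120 and 627 ± 119 normalized counts (SD, n = 5 each). These levels match the genotype on each label.

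**Figure D1:**
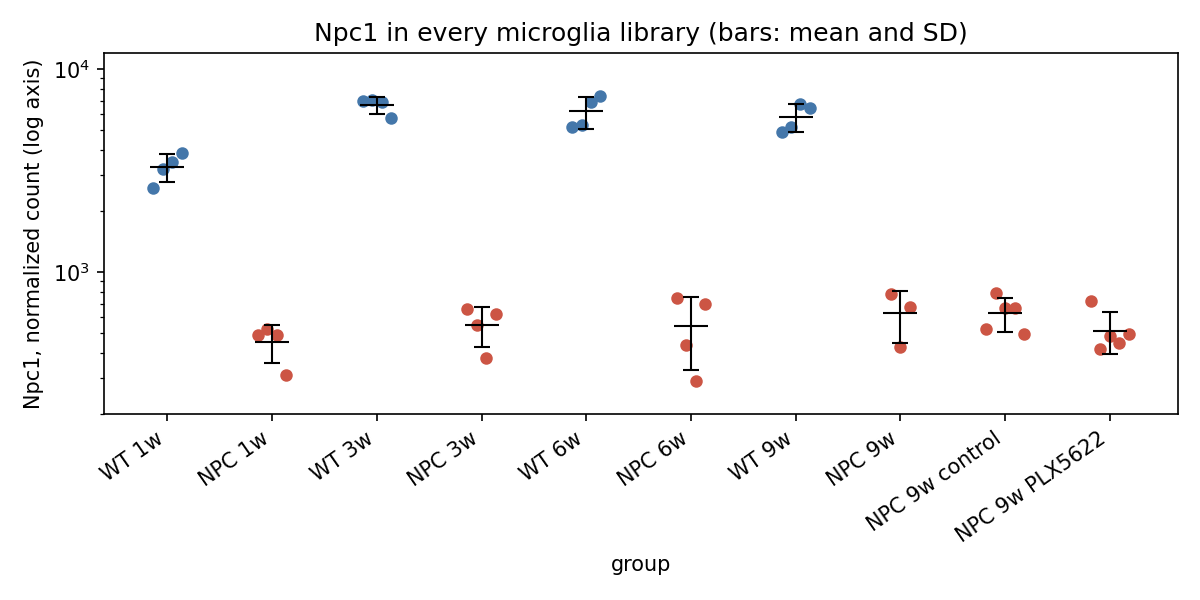
Normalized count of Npc1 on a log axis for each of the 41 libraries by group, with points for libraries and black bars for the group mean and SD. Every NPC library lies below every WT library, whose lowest value is 2606.

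The comparison at 1 week asked how NPC microglia differed from WT microglia early in life. A small set of genes already differed. Tmem154, a membrane protein, rose 3.46-fold (95% interval 2.47 to 4.85, adjusted p = 7.98e-05), from 198 ± 67.2 normalized counts in WT to 658 ± 87.7 in NPC (SD, n = 4 each). S1pr1, a receptor for sphingosine 1-phosphate, rose 2.85-fold (2.09 to 3.89, adjusted p = 0.000254), from 1335 ± 209 to 3785 ± 444. Serpinb1c, of the serine protease inhibitor family, rose 12.0-fold (4.32 to 33.4, adjusted p = 0.00646). The chemokine receptor Ccr1 fell from 4996 ± 734 to 1562 ± 208 normalized counts, a log2 change of -1.67 ± 0.27 (SE, adjusted p = 0.000798). Htra3, a secreted serine protease, fell by 1.86 on the log2 scale, the apolipoprotein Apoc1 by 2.05 and the sialomucin Cd34 by 1.40.

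Some gene lists differed at 1 week, none of them with an estimated correlation. Of 47 measured lysosome genes 4 rose and 0 fell (11 and 1 adjusted over the list alone), with a camera adjusted p of 1.37e-07 and an adjusted p = 0.684 with an estimated correlation. Atp6v1a, a subunit of the proton pump that acidifies lysosomes, rose 1.80-fold (1.51 to 2.14, adjusted p = 0.000255). The count of 4 lysosome genes was 1 without WT 1w replicate A, NPC 1w replicate B or NPC 1w replicate D, 2 without WT 1w replicate B, WT 1w replicate C or NPC 1w replicate A, and 8 without NPC 3w replicate C. The disease-associated list, genes that microglia raise around damage, had 3 of 39 members higher (5 up and 1 down adjusted over the list alone; camera adjusted p = 0.0256, adjusted p = 0.913 with an estimated correlation). Its adjusted p was 0.449 without WT 1w replicate A, 0.167 without WT 1w replicate B, 0.0693 without NPC 1w replicate B, 0.486 without NPC 1w replicate D and 0.0763 with the replicate block. The count of 3 was 0 without WT 1w replicate A or NPC 1w replicate D, 1 without WT 1w replicate B or NPC 1w replicate B and 5 without NPC 3w replicate C. Its leading genes at later ages did not pass. Cst7, a cystatin of lysosomes, had a log2 change of -0.15 (adjusted p = 0.938), and the receptor kinase Axl 0.02 (adjusted p = 0.994). Homeostatic genes, the signature of resting microglia, fell at 1 of 23 (4 adjusted over the list alone; camera adjusted p = 0.00344, adjusted p = 0.684 with an estimated correlation and 0.0808 without NPC 1w replicate D), and at 2 without NPC 1w replicate A. No member of the interferon, cell cycle or cholesterol lists passed in limma. The interferon list as a whole was higher (camera adjusted p = 0.00403, adjusted p = 0.831 with an estimated correlation, the highest over its alternatives), and its adjusted p was 0.7 without NPC 1w replicate A. Oligodendrocyte markers were lower as a list, with a mean log2 change of -1.08 and 0 of 14 past the threshold in limma (0 up and 1 down adjusted over the list alone; camera adjusted p = 0.00344, adjusted p = 0.684 with an estimated correlation, 0.0559 without WT 1w replicate D and 0.0506 without NPC 1w replicate B), and 2 fell without NPC 1w replicate D. Monocyte and neutrophil markers were higher as a list, with a median log2 change of 1.38 and 0 of 15 past the threshold in limma (0 adjusted over the list alone; camera adjusted p = 0.0244, adjusted p = 0.718 with an estimated correlation). Their adjusted p was 0.0536 without WT 1w replicate A, 0.105 without WT 1w replicate C, 0.115 without NPC 1w replicate C and 0.0974 without NPC 1w replicate D.

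Glycolysis genes were higher as a list at 1 week with 0 of 19 past the threshold in limma (0 adjusted over the list alone; camera adjusted p = 0.0137, adjusted p = 0.718 with an estimated correlation), at 0.13 without WT 1w replicate A, 0.0506 without NPC 1w replicate B and 0.0882 without NPC 1w replicate D. Inflammatory genes were lower as a list with 0 of 27 past it (0 up and 2 down adjusted over the list alone; camera adjusted p = 0.0244, adjusted p = 0.684 with an estimated correlation), at 0.0598 without WT 1w replicate A, 0.0559 without WT 1w replicate D, 0.0675 without NPC 1w replicate C and 0.0882 without NPC 1w replicate D. Without NPC 3w replicate C, 2 inflammatory genes fell. In all, 123 genes were higher and 81 lower at 1 week, with 1642 at an unadjusted p under 0.05 where chance gives 702.3. The total of 204 was 140 with the replicate block, 87 without WT 1w replicate A, 93 without NPC 1w replicate D, 128 without NPC 1w replicate C and 453 without NPC 3w replicate C.

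**Figure D2:**
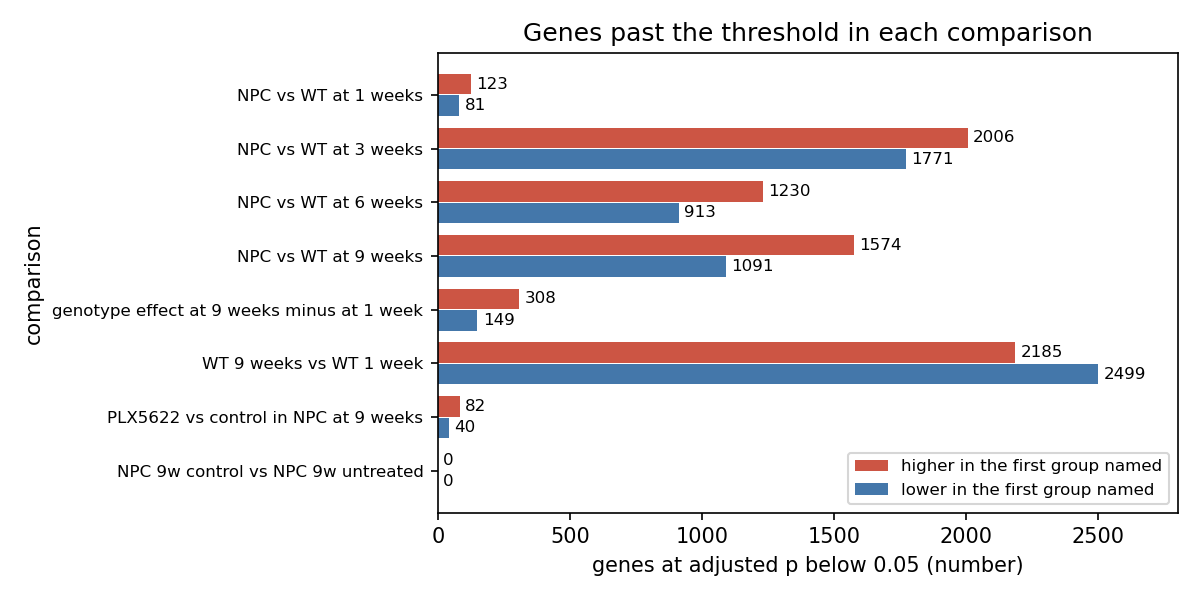
Number of genes at an adjusted p below 0.05 in each comparison, as bars from 0 for genes higher and lower in the group named first. NPC against WT gave 204 genes at 1 week and 3777, 2143 and 2665 at 3, 6 and 9 weeks.

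At 3 weeks NPC microglia differed from WT microglia in many more genes. Hpse, the heparan sulfate-degrading enzyme heparanase, rose 21.1-fold (12.5 to 35.4), from 89.5 ± 21.0 normalized counts in WT to 1978 ± 795 in NPC (SD, n = 4 each, adjusted p = 1.62e-09). The complement component C2 rose 31.5-fold (15.5 to 64.0, adjusted p = 3.43e-08). Of 39 measured disease-associated genes 31 rose and 1 fell (32 and 1 adjusted over the list alone; camera adjusted p = 3.19e-19, and 0.0476 with an estimated correlation). Cst7 rose 5.23-fold (3.45 to 7.94) and Axl 2.97-fold (2.14 to 4.12). Interferon genes rose at 29 of 37 and fell at 1 (29 and 1 adjusted over the list alone; camera adjusted p = 1.79e-19, and 0.0476 with an estimated correlation), among them Ifit2 5.83-fold and Ifi44 5.36-fold. Cell cycle genes rose at 21 of 34 (22 adjusted over the list alone; camera adjusted p = 1.16e-08, and 0.0476 with an estimated correlation), with the mitotic genes Ube2c at 4.62-fold and Kif23 at 4.51-fold. Glycolysis genes rose at 12 of 19 (13 adjusted over the list alone; camera adjusted p = 2.81e-09, and 0.0476 with an estimated correlation), with pyruvate kinase Pkm at 2.44-fold and Tpi1 at 2.71-fold.

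Lysosome genes rose at 30 of 47 and fell at 1 at 3 weeks (34 and 2 adjusted over the list alone; camera adjusted p = 2.91e-15, adjusted p = 0.103 with an estimated correlation). Cathepsin B, Ctsb, rose 3.19-fold and Atp6v1a 2.22-fold. Cholesterol genes rose at 6 of 25 and fell at 1 (6 and 1 adjusted over the list alone; camera adjusted p = 0.00677, adjusted p = 0.284 with an estimated correlation), with Dhcr7, the last enzyme of cholesterol synthesis, at 1.63-fold. Antigen presentation genes rose at 10 of 18 and fell at 2 (10 and 2 adjusted over the list alone; camera adjusted p = 0.000637, adjusted p = 0.345 with an estimated correlation), with the class I molecule H2-K1 at 4.13-fold. Inflammatory genes rose at 11 of 27 and fell at 2 (12 and 3 adjusted over the list alone; camera adjusted p = 0.0165, adjusted p = 0.284 with an estimated correlation and 0.0528 after quantile normalization), with the cytokine Il1b at 4.20-fold and the chemokine Ccl3 at 4.04-fold. Complement and Fc receptor genes rose at 9 of 16 and fell at 1 (10 and 1 adjusted over the list alone; camera adjusted p = 0.00677, adjusted p = 0.284 with an estimated correlation), with the receptor C3ar1 at 2.08-fold. LXR targets and lipid storage genes rose at 6 of 22 and fell at 2 (6 and 2 adjusted over the list alone; camera adjusted p = 0.0423, adjusted p = 0.284 with an estimated correlation and 0.161 after quantile normalization), with the lipid droplet protein Plin2 at 2.21-fold. Their adjusted p was 0.0697 without WT 3w replicate D and 0.059, 0.0803 and 0.0893 without NPC 3w replicates A, B and D. Homeostatic genes fell at 7 of 23 and rose at 3 (8 and 3 adjusted over the list alone; camera adjusted p = 0.0424, adjusted p = 0.393 with an estimated correlation, 0.0836 without WT 3w replicate C, 0.162 without NPC 3w replicate A and 0.0928 without NPC 3w replicate D). Selplg, a selectin ligand, fell by 1.16 on the log2 scale. Hs3st2, a heparan sulfate sulfotransferase, fell by 3.20, and the transcription factor Klf2 by 2.10.

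The 3-week differences depended in part on single libraries. In all, 2006 genes were higher and 1771 lower, a total of 3777 that was 2057 without NPC 3w replicate C, 2372 without WT 3w replicate A and 769 with the fit limited to the groups compared. Oxidative phosphorylation genes rose at 27 of 35 (34 adjusted over the list alone; camera adjusted p = 1.19e-10, adjusted p = 0.317 with an estimated correlation), but at 7 without NPC 3w replicate C, 10 without WT 3w replicate A and 16 without WT 3w replicate C. Without NPC 3w replicate C, cholesterol genes rose at 3, antigen presentation genes at 6 and homeostatic genes fell at 4, and cholesterol genes also rose at 3 without WT 3w replicate A. Without NPC 3w replicate A, 4 inflammatory genes fell. The 2 antigen presentation genes that fell were 0 without WT 3w replicates A or D or NPC 3w replicates A or D and 1 without WT 3w replicate B or NPC 3w replicate C. Tmem119, whose libraries overlapped, fell by 0.53 on the log2 scale (adjusted p = 0.0163), and its adjusted p was 0.0548 without NPC 3w replicate D and 0.103 with the fit limited to the groups compared, the highest over its alternatives. The higher genes had shorter transcripts (median 2460 bases) than the lower genes (4504.5), and across 13407 genes the log2 change fell with length (Spearman -0.308, or -0.183 without NPC 3w replicate C), genes not being independent replicates. Rescaling to the same total shifted the median of all genes by -0.14 on the log2 scale and gave 1503 higher and 2438 lower genes.

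At 6 weeks disease-associated, interferon, cell cycle and glycolysis genes were higher in NPC microglia, and 13 of 23 homeostatic genes were lower. Lox, the collagen-crosslinking lysyl oxidase, rose 31.7-fold (20.1 to 49.9), from 45.8 ± 22.0 normalized counts in WT to 1386 ± 273 in NPC (SD, n = 4 each, adjusted p = 1.28e-11). Hpse rose 41.4-fold (24.7 to 69.6), Serpinb1c 61.6-fold (22.2 to 171) and the glycoprotein Gpnmb 21.9-fold (7.10 to 67.5). Disease-associated genes rose at 35 of 39 (35 adjusted over the list alone; camera adjusted p = 6.56e-32, and 0.0087 with an estimated correlation), with Cst7 going from 164 ± 73.4 to 1963 ± 756 normalized counts, an 11.9-fold rise (7.85 to 18.1), and Axl rising 5.35-fold. Interferon genes rose at 31 of 37 (32 up and 1 down adjusted over the list alone; camera adjusted p = 1.81e-29, and 0.0135 with an estimated correlation), with Ifit2 at 9.11-fold. Cell cycle genes rose at 24 of 34 (30 adjusted over the list alone; camera adjusted p = 3.2e-17, and 0.00277 with an estimated correlation), with the replication helicase subunits Mcm2 at 2.13-fold (1.76 to 2.58) and Mcm6 at 2.69-fold (2.04 to 3.55). Glycolysis genes rose at 10 of 19 (12 adjusted over the list alone; camera adjusted p = 5.99e-10, and 0.0305 with an estimated correlation), with Pkm at 2.76-fold.

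Homeostatic genes fell at 13 of 23 and rose at 1 at 6 weeks (15 and 2 adjusted over the list alone; camera adjusted p = 5.4e-07, adjusted p = 0.0518 with an estimated correlation). Selplg fell by 1.35 on the log2 scale and the purinergic receptor P2ry12 by 0.88. The anti-angiogenic factor Serpinf1 went from 14507 ± 3956 normalized counts to 1603.5 ± 32.0, a log2 change of -3.13 ± 0.18 (SE, adjusted p = 1.82e-12), and Ccr1 fell by 3.34. Lysosome genes rose at 29 of 47 (31 adjusted over the list alone; camera adjusted p = 6.71e-15, adjusted p = 0.08 with an estimated correlation), including Ctsb at 2.87-fold. Inflammatory genes rose at 13 of 27 and fell at 3 (14 and 4 adjusted over the list alone; camera adjusted p = 3.18e-05, adjusted p = 0.0603 with an estimated correlation), with Ccl3 at 6.34-fold and Il1b at 3.24-fold. Cholesterol genes rose at 7 of 25 (8 adjusted over the list alone; camera adjusted p = 0.0017, adjusted p = 0.152 with an estimated correlation), with their master regulator Srebf2 at 1.73-fold. LXR targets and lipid storage genes rose at 9 of 22 and fell at 3 (10 and 5 adjusted over the list alone; camera adjusted p = 0.00665, adjusted p = 0.139 with an estimated correlation), with the fatty acid carrier Fabp5 at 9.32-fold. Antigen presentation genes rose at 4 of 18 and fell at 1 (5 and 2 adjusted over the list alone; camera adjusted p = 0.0325, adjusted p = 0.603 with an estimated correlation). Their adjusted p was 0.0793 without WT 6w replicate A, 0.139 without WT 6w replicate C or NPC 6w replicate C and 0.11 without NPC 6w replicate B. Complement and Fc receptor genes rose at 5 of 16 and fell at 1 (6 and 1 adjusted over the list alone; camera adjusted p = 0.0325, adjusted p = 0.388 with an estimated correlation). Their adjusted p was 0.139 without WT 6w replicate C, 0.0718 without NPC 6w replicate B and 0.101 without NPC 6w replicate C. Without either of these NPC libraries, 3 rose. Oxidative phosphorylation genes rose at 1 of 35 (0 adjusted over the list alone; camera adjusted p = 0.000138, adjusted p = 0.594 with an estimated correlation), or 6 without NPC 6w replicate D and 8 without NPC 3w replicate C.

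Astrocyte RNA differed between libraries at 6 weeks, and fewer genes passed when it was allowed for. Gfap, an astrocyte filament protein, rose 12.1-fold (5.29 to 27.8) from 77.9 ± 34.4 to 1345 ± 1141 normalized counts (SD, n = 4 each), with NPC 6w replicates B and C the highest in astrocyte markers. In all, 1230 genes were higher and 913 lower, a total of 2143 that was 872 without both of these libraries, 1183 with the astrocyte score as covariate and 3277 without NPC 3w replicate C. Without both libraries 27 disease-associated, 26 interferon, 18 cell cycle, 12 lysosome, 9 inflammatory, 6 glycolysis, 5 LXR, 2 antigen presentation, 2 complement and 1 cholesterol genes rose and 8 homeostatic genes fell. With the astrocyte score as covariate 3 cholesterol, 3 complement and 0 oxidative phosphorylation genes rose and 7 homeostatic genes fell, both alternatives chosen after seeing the data. Leaving out both libraries leaves fewer mice to test, and the score contains Gfap, which itself rose in NPC. Lower counts could follow from either alone, so they do not show a link to astrocyte RNA. The 3 inflammatory genes that fell were 1 without WT 6w replicate A, WT 6w replicate B, NPC 6w replicate A or NPC 6w replicate D.

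At 9 weeks, the latest age, disease-associated genes were higher and homeostatic genes lower in NPC microglia. Cst7 rose 17.4-fold (11.1 to 27.3) from 168 ± 50.0 normalized counts in WT (SD, n = 4) to 2846 ± 149.7 in NPC (SD, n = 3, adjusted p = 1.72e-10). Axl rose 8.91-fold (6.26 to 12.7) to 37279.9 ± 6299 normalized counts, Hpse 43.4-fold (24.8 to 76.1), Lox 36.6-fold (22.4 to 59.9) and C2 38.2-fold (17.8 to 82.2). Disease-associated genes rose at 34 of 39 (35 adjusted over the list alone; camera adjusted p = 7.03e-29, and 0.019 with an estimated correlation). Homeostatic genes fell at 14 of 23 (16 adjusted over the list alone; camera adjusted p = 5.07e-11, and 0.019 with an estimated correlation), with Selplg falling by 1.84, the secreted glycoprotein Olfml3 by 1.14 and the sort marker Tmem119 by 1.11 on the log2 scale. The orphan receptor Gpr165 went from 10093 ± 1694 to 701 ± 122 normalized counts, a log2 change of -3.85 ± 0.23 (SE, adjusted p = 1.17e-12). Gp9, a platelet glycoprotein, fell by 3.50, and Hs3st2 by 5.60.

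Lysosome genes rose at 28 of 47 and fell at 1 at 9 weeks (29 and 3 adjusted over the list alone; camera adjusted p = 1.13e-11, adjusted p = 0.126 with an estimated correlation), and 3 fell without NPC 3w replicate C, with Ctsb at 3.17-fold (2.47 to 4.08) and Atp6v1a at 3.12-fold (2.58 to 3.77). Cholesterol genes rose at 10 of 25 (11 adjusted over the list alone; camera adjusted p = 0.000707, adjusted p = 0.126 with an estimated correlation), with squalene epoxidase Sqle at 3.02-fold (2.23 to 4.09) and Srebf2 at 1.84-fold, and at 5 without NPC 9w replicate A and 4 with the astrocyte score as covariate. LXR targets and lipid storage genes rose at 10 of 22 and fell at 2 (11 and 4 adjusted over the list alone; camera adjusted p = 0.00525, adjusted p = 0.126 with an estimated correlation), with Fabp5 at 10.6-fold and the droplet protein Plin3 at 2.93-fold. Interferon genes rose at 29 of 37 (32 adjusted over the list alone; camera adjusted p = 6.67e-21, adjusted p = 0.0524 with an estimated correlation), with Ifit2 at 8.40-fold. Inflammatory genes rose at 13 of 27 and fell at 2 (13 and 2 adjusted over the list alone; camera adjusted p = 0.000108, adjusted p = 0.126 with an estimated correlation), with Ccl3 at 9.95-fold (5.86 to 16.9) and Il1b at 3.95-fold (2.84 to 5.49). Glycolysis genes rose at 10 of 19 (12 adjusted over the list alone; camera adjusted p = 3.19e-05, adjusted p = 0.126 with an estimated correlation), with Pkm at 2.63-fold.

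Smaller parts of the remaining lists passed at 9 weeks. Antigen presentation genes rose at 6 of 18 and fell at 2 (6 and 2 adjusted over the list alone, camera adjusted p = 0.116), with H2-K1 at 4.61-fold, and rose at 3 without NPC 9w replicate A. The 2 that fell were 0 without NPC 9w replicate C and 1 without WT 9w replicate A or NPC 9w replicate B. Complement and Fc receptor genes rose at 3 of 16 and fell at 3 (5 and 3 adjusted over the list alone; camera adjusted p = 0.504), with the central complement protein C3 at 12.4-fold, counts that were 2 and 1 without NPC 9w replicate A and 5 and 4 without NPC 3w replicate C. Immediate early and stress genes, which respond within minutes to stimuli and to handling of the cells, rose at 10 of 26 and fell at 1 (14 and 2 adjusted over the list alone), with Nr4a1 at 3.28-fold. Their camera adjusted p was 0.00525, and adjusted p = 0.376 with an estimated correlation and 0.404 without NPC 9w replicate C, where 3 fell. Oxidative phosphorylation genes rose at 6 of 35 (6 adjusted over the list alone; camera adjusted p = 6.69e-05, adjusted p = 0.546 with an estimated correlation), with succinate dehydrogenase subunit Sdha at 1.45-fold, and at 2 without NPC 9w replicate A, 3 without NPC 9w replicate C, 13 without NPC 3w replicate C and 1 with the astrocyte score as covariate, an alternative chosen after seeing the data. Cell cycle genes rose at 4 of 34 (4 adjusted over the list alone; camera adjusted p = 0.0635), or 8 without NPC 3w replicate C, and the difference from 6 weeks was not tested. In all, 1574 genes were higher and 1091 lower, a total of 2665 that was 1641 without NPC 9w replicate A, 1666 with the astrocyte score as covariate and 4429 with the fit limited to the groups compared.

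**Figure D3:**
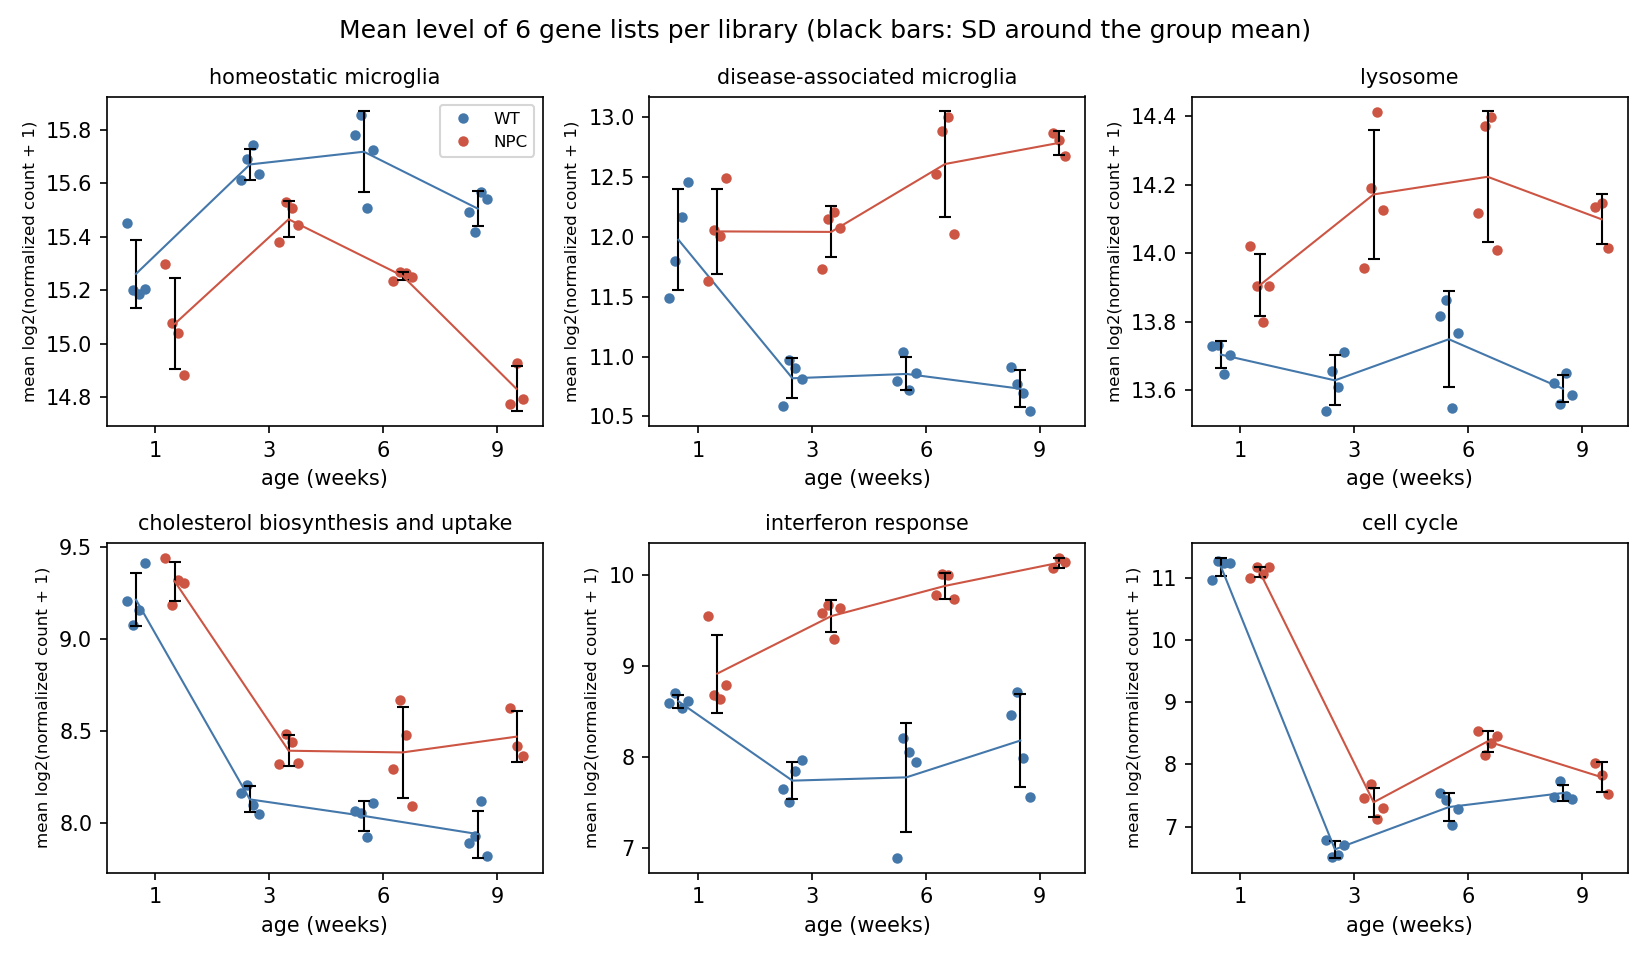
Mean log2(normalized count + 1) of 6 gene lists in each library against age in weeks, with points for WT and NPC libraries, lines through the group means and black bars for the SD. The homeostatic list fell at 14 of 23 genes and the disease-associated list rose at 34 of 39 genes in NPC at 9 weeks.

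Markers of other cells were low against microglial genes but some moved with the genotype. At 9 weeks 2 of 13 astrocyte and Bergmann glia markers rose (4 adjusted over the list alone, camera adjusted p = 0.0652), or 4 without NPC 3w replicate C and 1 without NPC 9w replicate A. Gfap was at 17.4-fold (7.11 to 42.6), 1413 ± 772 normalized counts in NPC (SD, n = 3) against 73.0 ± 7.37 in WT (SD, n = 4). At 6 weeks the astrocyte list passed as a whole, with 2 of 13 higher (5 up and 1 down adjusted over the list alone; camera adjusted p = 0.0158, adjusted p = 0.388 with an estimated correlation). Its adjusted p was 0.0948 without WT 6w replicate C, 0.0657 without NPC 6w replicate B and 0.0661 without NPC 6w replicate C. Of its genes 4 rose without WT 6w replicate A, WT 6w replicate D or NPC 3w replicate C and 7 without NPC 6w replicate D. Without NPC 6w replicate B 1 rose, and without both NPC 6w replicates B and C 1 rose and 1 fell. At 3 weeks Gfap rose 4.79-fold. Border-associated macrophage markers rose at 4 of 12 at 3 weeks (5 adjusted over the list alone; camera adjusted p = 0.0331, adjusted p = 0.284 with an estimated correlation, 0.0559 without WT 3w replicate D, 0.0517 without NPC 3w replicate A and 0.109 without NPC 3w replicate D). At 9 weeks 4 of 12 rose and 0 fell (4 and 0 adjusted over the list alone; camera adjusted p = 0.0904), with Ms4a7 at 13.6-fold and the mannose receptor Mrc1 at 2.53-fold. Mrc1 also rose 2.45-fold at 3 weeks, where the groups overlapped, and 2.41-fold at 6 weeks. The endothelial and pericyte list had 1 of 14 lower at 9 weeks (1 adjusted over the list alone; camera adjusted p = 0.992), the adhesion molecule Pecam1 at a log2 change of -1.40. Neuron markers rose at 1 of 14 (camera adjusted p = 0.965), oligodendrocyte and myelin markers at 1 of 14 (camera adjusted p = 0.504) and lymphocyte markers at 1 of 4 (camera adjusted p = 0.213). Monocyte and neutrophil markers fell at 1 of 15 (camera adjusted p = 0.094), and 0 of 3 erythrocyte markers passed (camera adjusted p = 0.439). The counts adjusted over the list alone were 1, 0, 1, 1 and 0 for these 5 lists.

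Itgam, which encodes the sort marker CD11b, and Csf1r, the receptor that PLX5622 inhibits, also differed between groups. Itgam fell at 3 weeks from 63446 ± 4300 normalized counts in WT to 41401 ± 15436 in NPC (SD, n = 4 each), a log2 change of -0.72 (limma adjusted p = 0.0123). That value was 0.0631 without NPC 3w replicate C and 0.167 with the fit limited to the groups compared, the highest over its alternatives. At 9 weeks Itgam fell from 53181 ± 8692 (SD, n = 4) to 31208 ± 5163 (SD, n = 3), a log2 change of -0.77 (limma adjusted p = 0.0151). That value was 0.0568 without WT 9w replicate C, 0.0722 without NPC 9w replicate A, 0.0705 without NPC 9w replicate C and 0.0801 with the astrocyte score as covariate, an alternative chosen after seeing the data. After quantile normalization it was 0.0963, the highest over its alternatives. Csf1r fell at 3 weeks by 0.40 on the log2 scale (limma adjusted p = 0.0241). Its value was 0.0575 without WT 3w replicate A, 0.163 without NPC 3w replicate C and 0.184 with the fit limited to the groups compared, the highest over its alternatives. Itgam did not pass at 1 and 6 weeks (adjusted p = 0.835 and 0.203), but at 6 weeks its adjusted p was 0.0179 without NPC 3w replicate C, the lowest over its alternatives, and at most 0.759. Csf1r did not pass at 1, 6 and 9 weeks (adjusted p = 0.939, 0.154 and 0.122). At 6 weeks its adjusted p was 0.0373 without NPC 3w replicate C and from 0.00726 to 0.335 over its alternatives, and at 9 weeks from 0.00718 to 0.363. With WT age Itgam rose 1.74-fold (1.30 to 2.34, adjusted p = 0.0035) and Csf1r 1.37-fold (1.14 to 1.64, adjusted p = 0.00741, and 0.132 after quantile normalization, the highest over its alternatives).

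The NPC calls overlapped between ages. The ages share no library, but their tests share 1 estimate of spread per gene, which can itself raise the overlap. Genes are also not independent replicates. Of 123 genes higher at 1 week, 103 were also higher at 9 weeks where independence would give 13.8, and of 81 lower genes 64 were also lower at 9 weeks where independence would give 6.29. Between 6 and 9 weeks 929 higher and 565 lower genes were shared, against 138 and 70.9. At all 4 ages 92 genes were higher and 51 lower, among them Atp6v1a and Ctsb among the higher genes and Ccr1, Cd34 and Serpinf1 among the lower. The total of 143 was 69 without WT 1w replicate A, 71 without NPC 1w replicate D and 277 without NPC 3w replicate C. At 3, 6 and 9 weeks together 736 genes were higher and 340 lower.

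The interaction asked whether the NPC difference itself had changed between 1 and 9 weeks. It had moved upward for disease-associated, interferon and inflammatory genes. The inflammatory list had a mean log2 change of -0.21 at 1 week and 1.02 at 9 weeks. At 1 week 0 of its 27 genes passed, with a camera adjusted p of 0.0244 and 0.684 with an estimated correlation. A turn of direction is therefore not shown. For Cst7 the difference was larger at 9 weeks by 4.27 ± 0.43 on the log2 scale (SE, adjusted p = 7.39e-07), for Axl by 3.14 ± 0.34 (adjusted p = 2.07e-06) and for the lipoprotein lipase Lpl by 2.52 ± 0.44 (adjusted p = 0.00073). A fall in WT was part of this. The mean log2 level of disease-associated genes went from 11.98 to 10.73 in WT and from 12.05 to 12.79 in NPC. Lpl fell with age in WT by more than 2.52, so it did not rise with age in NPC. Interferon genes went from 8.61 to 8.18 in WT and from 8.92 to 10.14 in NPC. Disease-associated genes passed upward at 22 of 39 (33 adjusted over the list alone; camera adjusted p = 7.4e-36, and 0.00972 with an estimated correlation). Interferon genes passed upward at 15 of 37 (27 adjusted over the list alone; camera adjusted p = 5.32e-22, and 0.0262 with an estimated correlation), with the chemokine Cxcl10 at 3.63 ± 0.65. Inflammatory genes passed upward at 9 of 27 and downward at 1 (16 and 1 adjusted over the list alone; camera adjusted p = 8.88e-10, and 0.011 with an estimated correlation), with Il1b at 2.35 ± 0.32 and Ccl3 at 3.06 ± 0.51. LXR targets passed upward at 8 of 22 (10 up and 2 down adjusted over the list alone, camera adjusted p = 8.14e-06, and 0.02 with an estimated correlation). Apoc1, which was lower in NPC at 1 week, was among them at 3.79 ± 0.58. The addressin Madcam1 showed the largest named rise, 5.12 ± 1.04 (adjusted p = 0.00388).

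The NPC difference moved downward between these ages for Gpr165, by a log2 change of -2.76 ± 0.32 (SE, adjusted p = 5.01e-06), and for Trp53i11, by -2.86 ± 0.42 (adjusted p = 8.51e-05). Homeostatic genes passed downward at 4 of 23 (10 adjusted over the list alone; camera adjusted p = 2.67e-09, and 0.02 with an estimated correlation), or 2 without NPC 9w replicate A and 7 without NPC 1w replicate D or NPC 3w replicate C. Olfml3 was among them at -0.89 ± 0.19 (adjusted p = 0.00694), with an adjusted p of 0.0741 with the replicate block and 0.122 with all 41 libraries in one fit, the highest over its alternatives. Lysosome genes passed upward at 9 of 47 (14 adjusted over the list alone; camera adjusted p = 5.79e-07, adjusted p = 0.253 with an estimated correlation), including the tetraspanin Cd63 at 1.67 ± 0.37. That count was 3 without NPC 9w replicate A, 4 without WT 9w replicate D or NPC 1w replicate C, and 5 without WT 9w replicate C or NPC 9w replicate B. Tmem119 did not pass (log2 change -0.64, adjusted p = 0.162). In all, 308 genes passed upward and 149 downward, a total of 457 that was 270 with the replicate block, 235 without NPC 9w replicate A and 835 without NPC 3w replicate C.

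Markers of other cells also moved as lists in the interaction. Monocyte and neutrophil markers were lower, with a mean of -1.56 and 0 of 15 past the threshold in limma (0 up and 2 down adjusted over the list alone; camera adjusted p = 0.00039, adjusted p = 0.206 with an estimated correlation). Oligodendrocyte markers were higher, with a mean of 1.57 and 0 of 14 past it (2 up and 0 down adjusted over the list alone; camera adjusted p = 0.00455, adjusted p = 0.259 with an estimated correlation), or 2 without WT 1w replicate B or NPC 9w replicate C. Border-associated macrophage markers passed upward at 1 of 12 (2 adjusted over the list alone; camera adjusted p = 0.0483, adjusted p = 0.259 with an estimated correlation and 0.0842 after quantile normalization), or 2 without NPC 3w replicate C. Their adjusted p was 0.0713 and 0.124 without WT 1w replicates C and D, 0.0789 and 0.136 without WT 9w replicates B and C, 0.0924 and 0.079 without NPC 1w replicates A and B, and 0.0968 and 0.156 without NPC 9w replicates A and B.

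Further lists were higher in the interaction, and none of these passed with an estimated correlation. Cholesterol genes passed upward at 3 of 25 (3 adjusted over the list alone; camera adjusted p = 0.000403, adjusted p = 0.157 with an estimated correlation), or 1 without WT 9w replicate D or NPC 9w replicate A. Glycolysis genes passed upward at 4 of 19 (5 adjusted over the list alone; camera adjusted p = 0.00039, adjusted p = 0.206 with an estimated correlation), Pkm at 1.22 ± 0.19 among them. That count was 2 without WT 1w replicate C and 1 without WT 1w replicate D, WT 9w replicates B or C, NPC 1w replicates A or C or NPC 9w replicates A or C. Oxidative phosphorylation genes passed at 0 of 35 in limma (0 adjusted over the list alone; camera adjusted p = 3.96e-05, adjusted p = 0.496 with an estimated correlation). Cell cycle genes passed at 0 of 34 (0 adjusted over the list alone; camera adjusted p = 0.0101, adjusted p = 0.259 with an estimated correlation and 0.0858 without NPC 9w replicate A). Immediate early and stress genes passed at 0 of 26 (11 up adjusted over the list alone; camera adjusted p = 0.00039, adjusted p = 0.206 with an estimated correlation and 0.165 without NPC 9w replicate C), or 7 without NPC 9w replicate B and 3 without NPC 3w replicate C. Antigen presentation genes passed upward at 2 of 18 (2 adjusted over the list alone; camera adjusted p = 0.0138, adjusted p = 0.496 with an estimated correlation and 0.0667 with the replicate block). Their adjusted p was 0.0746 without WT 9w replicate D, 0.0828 without NPC 1w replicate D and 0.0969 without NPC 9w replicate A. Their count was 1 without WT 1w replicates B or D, WT 9w replicates C or D, NPC 1w replicates B, C or D or NPC 9w replicates A or B.

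WT microglia themselves changed with age, which the comparison of WT mice at 9 weeks and 1 week describes as a background for the NPC course. Proliferation genes were lower at 9 weeks than at 1 week. All 34 cell cycle genes fell (34 adjusted over the list alone; camera adjusted p = 5.34e-45, and 2.27e-06 with an estimated correlation), with the helicase subunit Mcm5 going from 5766 ± 692 to 726 ± 118 normalized counts (SD, n = 4 each), a log2 change of -2.99 ± 0.15, and the kinesin Kif4 with a log2 change of -5.99. Cholesterol genes fell at 20 of 25 (21 adjusted over the list alone; camera adjusted p = 1.11e-10, and 0.00763 with an estimated correlation), with Sqle falling by 3.31 and Srebf2 by 1.35. Disease-associated genes fell at 22 of 39 and rose at 2 (22 and 2 adjusted over the list alone; camera adjusted p = 1.67e-06, adjusted p = 0.446 with an estimated correlation), with Lpl falling by 3.80 and the growth factor Igf1 by 4.29. Oxidative phosphorylation genes fell at 30 of 35 (34 adjusted over the list alone; camera adjusted p = 2.02e-10, adjusted p = 0.47 with an estimated correlation), with Cox5a falling by 1.43 and Atp5b by 0.85. LXR targets fell at 10 of 22 and rose at 3 (10 and 4 adjusted over the list alone; camera adjusted p = 0.0248, adjusted p = 0.446 with an estimated correlation), with Plin2 falling by 1.87, and 5 rose without NPC 3w replicate C.

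Part of the homeostatic genes rose with age, 10 of 23 against 3 that fell (10 and 3 adjusted over the list alone), while the list as a whole did not pass (camera adjusted p = 0.0516), with Selplg at 3.79-fold (2.98 to 4.84) and Tmem119 at 2.69-fold (2.15 to 3.37). Tgm2, a protein-crosslinking transglutaminase, rose 22.7-fold, from 491 ± 307 to 9776 ± 479.9 normalized counts (SD, n = 4 each, adjusted p = 2.73e-12), and Npc1 rose 1.76-fold (1.26 to 2.47). Antigen presentation genes rose at 5 of 18 (5 adjusted over the list alone; camera adjusted p = 0.0143, adjusted p = 0.565 with an estimated correlation), with H2-T23 at 2.35-fold, or 3 without WT 1w replicate D. Lysosome genes went both ways, with 7 higher and 14 lower of 47 (7 and 15 adjusted over the list alone; camera adjusted p = 0.122). The sulfamidase Sgsh rose 2.28-fold and the beta-glucuronidase Gusb fell by 1.07 on the log2 scale. Among markers of other cells, border-associated macrophage genes fell at 3 of 12 (camera adjusted p = 0.0267, adjusted p = 0.446 with an estimated correlation and 0.0515 without WT 9w replicate C). Oligodendrocyte genes fell at 8 of 14 and rose at 1 (9 and 1 adjusted over the list alone). Monocyte and neutrophil genes rose at 3 of 15 and fell at 1 (3 and 1 adjusted over the list alone), or rose at 8 without WT 9w replicate D. Both lists had a camera adjusted p of 0.0152, and adjusted p = 0.47 with an estimated correlation. The macrophage receptors Mrc1 and Folr2 fell by 4.96 and 2.40 and the oligodendrocyte precursor receptor Pdgfra by 4.94, while the monocyte receptor Ccr2 rose 3.46-fold. In all, 2185 genes rose and 2499 fell, or 1825 and 2902 with the same total for every library and 2674 and 2476 after quantile normalization. The higher genes had longer transcripts (median 3928 bases) than the lower genes (2617). Across 13407 genes the log2 change increased with length (Spearman 0.205, genes not being independent replicates).

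PLX5622 was compared with control in NPC mice at 9 weeks, to describe microglia that remained during inhibition of Csf1r. The Fc receptor Fcgr4 rose 2.69-fold (2.18 to 3.32), from 479 ± 60.9 normalized counts in control to 1296 ± 202 with PLX5622 (SD, n = 5 each, adjusted p = 0.00108). Axl rose 1.71-fold (1.47 to 1.99) from 37415 ± 5213 to 63624 ± 2838 normalized counts (adjusted p = 0.00703). Emilin2, an extracellular matrix glycoprotein, rose 8.10-fold (4.56 to 14.4), the hyaluronan receptor Cd44 4.83-fold (2.94 to 7.94) and H2-DMa, which loads peptides on class II molecules, 2.01-fold (1.61 to 2.52). Cst3, the secreted protease inhibitor cystatin C, fell by 0.92 ± 0.13 on the log2 scale (SE, adjusted p = 0.0103), with an adjusted p of 0.136 after quantile normalization, the highest over its alternatives. Sema4b, a semaphorin, fell by 1.65. Csf1r itself did not pass, with 456725 ± 54500 normalized counts against 481216 ± 25354 (log2 change -0.08, adjusted p = 0.752), and neither did Tmem119 (-0.18, adjusted p = 0.671).

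**Figure D4:**
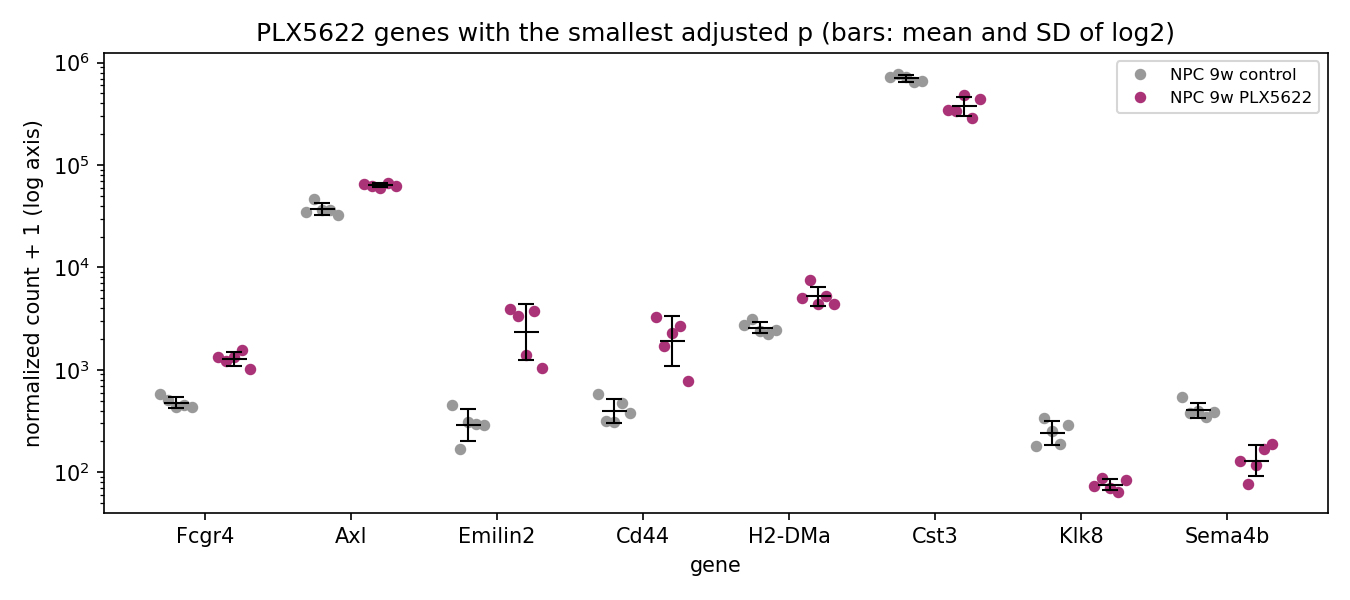
Normalized count + 1 on a log axis for the 8 named genes with the smallest adjusted p under PLX5622, with points for libraries and black bars for the mean and SD of the log2 values. In all 8 genes the 5 PLX5622 libraries lie apart from the 5 control libraries, as for Fcgr4 at 1296 ± 202 against 479 ± 60.9.

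Some members of the gene lists passed under PLX5622, and no list passed with an estimated correlation. Cholesterol genes rose at 4 of 23 (9 adjusted over the list alone; camera adjusted p = 1.11e-07, adjusted p = 0.328 with an estimated correlation). Homeostatic genes fell at 4 of 23 (7 down and 1 up adjusted over the list alone; camera adjusted p = 6.92e-07, adjusted p = 0.328 with an estimated correlation), including Cst3. Complement and Fc receptor genes rose at 2 of 16 (4 up and 1 down adjusted over the list alone; camera adjusted p = 0.00662, adjusted p = 0.328 with an estimated correlation), Fcgr4 and the anaphylatoxin receptor C5ar1, the latter 3.18-fold (2.16 to 4.68). Disease-associated genes rose at 3 of 39 (5 up and 4 down adjusted over the list alone; camera adjusted p = 0.938), with a median log2 change of -0.06 and a mean of 0.05, and 1 of 48 lysosome genes rose (camera adjusted p = 0.682). Without PLX5622 replicates 2, 3 or 4 or control replicates 3, 4 or 5, 0 cholesterol genes rose. Cholesterol genes rose at 2 without PLX5622 replicate 1 or control replicate 1 and at 1 without control replicate 2. Homeostatic genes fell at 1 without PLX5622 replicates 2 or 4 or control replicates 2 or 5, and at 2 without PLX5622 replicate 3 or control replicates 3 or 4. Disease-associated genes rose at 1 without PLX5622 replicate 4 or control replicates 3, 4 or 5. Without PLX5622 replicate 5, 4 rose and 3 fell. Complement and Fc receptor genes rose at 1 without control replicate 5.

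Lists of other functions and cells were also higher under PLX5622. Interferon genes passed at 0 of 37 in limma (6 up and 1 down adjusted over the list alone; camera adjusted p = 0.000171, adjusted p = 0.538 with an estimated correlation). Antigen presentation genes rose at 1 of 17 (3 adjusted over the list alone; camera adjusted p = 0.00168, adjusted p = 0.347 with an estimated correlation). Glycolysis genes passed at 0 of 19 in limma (4 up adjusted over the list alone; camera adjusted p = 0.0153, adjusted p = 0.328 with an estimated correlation, 0.11 without PLX5622 replicate 5 and 0.0869 without control replicate 1). Cell cycle genes passed at 0 of 34 in limma (0 adjusted over the list alone; camera adjusted p = 0.0268, adjusted p = 0.73 with an estimated correlation). Their adjusted p was 0.105 without PLX5622 replicate 1, 0.974 without PLX5622 replicate 2, the highest over the alternatives and with the direction turned to lower, 0.266 without control replicate 1 and 0.102 without control replicate 4. Border-associated macrophage markers rose at 2 of 9 (4 up and 1 down adjusted over the list alone; camera adjusted p = 0.0153, adjusted p = 0.328 with an estimated correlation, 0.0689 without PLX5622 replicate 1 and 0.0559 without PLX5622 replicate 4). The count of 2 was 0 without PLX5622 replicates 1 or 4 or control replicates 2, 3, 4 or 5, and 1 without PLX5622 replicates 2 or 3 or control replicate 1. Without PLX5622 replicate 5, 3 rose and 1 fell. Monocyte and neutrophil markers had a median log2 change of 2.65 with 0 of 15 past the threshold in limma (camera adjusted p = 0.00168, adjusted p = 0.449 with an estimated correlation).

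PLX5622 changed 82 genes upward and 40 downward, with 1931 at an unadjusted p under 0.05 where chance gives 643.85. The total of 122 was 21 without control replicate 5, 29 without control replicate 4, 33 without control replicate 3, 35 without control replicate 2, 38 without PLX5622 replicate 4, 47 without PLX5622 replicate 2, 62 without PLX5622 replicate 3 and 465 without PLX5622 replicate 5. With the monocyte and neutrophil score as covariate, an alternative chosen after seeing the data, 4 genes passed. All 122 log2 changes kept their sign with a median ratio of 0.933 (lower quartile 0.848), while the median SE grew 1.23-fold, so the lost calls do not show the score to be the cause. Under that covariate the adjusted p was 0.0827 for Emilin2, 0.0943 for Axl, 0.125 for H2-DMa, 0.14 for Cd44 and 0.141 for Sema4b, while Fcgr4 passed in every alternative.

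The PLX5622 calls were set against the NPC calls at 9 weeks, to ask whether treatment moved NPC genes back toward WT. Of the genes higher in NPC, 31 also rose with PLX5622 where independence would give 9.61, Axl and Cd44 among them, and of those lower in NPC 13 also fell, against 3.29, with Cst3 among them (Fisher p = 8.91e-10 and 1.08e-05, genes not being independent replicates). Toward WT, 12 genes lower in NPC rose, against 6.66, and 6 higher in NPC fell, against 4.74 (Fisher p = 0.0403 and 0.467). H2-DMa was 1 of the 12, at a log2 change of -1.06 in NPC and 1.01 with PLX5622. Across 12798 genes the Spearman correlation of the changes was 0.207. The 44 genes of shared direction were 10, 12, 13 and 16 without control replicates 5, 4, 3 and 2, 17, 22 and 27 without PLX5622 replicates 4, 2 and 3, and 123 without PLX5622 replicate 5. The number of genes moved toward WT also changed severalfold when single libraries were left out, with the range given in the section on processing.

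The control mice of the PLX5622 arm and the untreated NPC mice of the time course shared genotype and age, so their comparison describes differences between the arms, sex included. Xist, a gene of female cells, was at 653 and 757 normalized counts in control replicates 1 and 5, against 8.76 to 13.3 in the other controls and 4.66 to 36.7 in untreated mice. No gene passed in limma, with 598 at an unadjusted p under 0.05 where chance gives 715.6. edgeR called 0 with 449 and DESeq2 called 1 with 429. Npc1 was at 627 ± 119 in control (SD, n = 5) and 629.0 ± 181 in untreated mice (SD, n = 3). Astrocyte markers were lower as a list in control (camera adjusted p = 0.000108, adjusted p = 0.327 with an estimated correlation), and Gja1, a gap junction protein of astrocytes, had a log2 change of -1.72 (adjusted p = 0.828). Endothelial markers were also lower as a list (camera adjusted p = 0.00144, adjusted p = 0.18 with an estimated correlation and 0.0917 without NPC 9w replicate B), with Egfl7 at -1.53 (adjusted p = 0.566). In the other 6 lists past the camera threshold 0 members passed, also adjusted over the list alone. Neuron markers were lower (camera adjusted p = 0.0243, adjusted p = 0.327 with an estimated correlation, 0.133 without NPC 9w replicate B and 0.259 after quantile normalization). Oligodendrocyte markers were lower as well (camera adjusted p = 0.0253, adjusted p = 0.6 with an estimated correlation). The oligodendrocyte value was 0.0569 without NPC 9w replicate A, 0.0809 without NPC 9w replicate B, 0.104 without control replicate 3 and 0.128 after quantile normalization.

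Microglial lists also differed between control and untreated NPC mice. Immediate early genes were higher in control (camera adjusted p = 0.00119, adjusted p = 0.6 with an estimated correlation, 0.253 without NPC 9w replicate B, 0.271 without control replicate 1 and 0.19 without control replicate 2). Lysosome genes were higher (camera adjusted p = 0.0123, adjusted p = 0.689 with an estimated correlation, 0.486 without NPC 9w replicate C and 0.0573 without control replicate 2). LXR targets were higher (camera adjusted p = 0.0253, adjusted p = 0.327 with an estimated correlation and 0.11 after quantile normalization), at 0.0626 without NPC 9w replicate B, 0.191 without NPC 9w replicate C and 0.0763 without control replicate 1. Antigen presentation genes were lower (camera adjusted p = 0.0243, adjusted p = 0.689 with an estimated correlation), at 0.427 without NPC 9w replicate A, 0.0569 without control replicate 4 and 0.0941 without control replicate 5.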

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

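A total of 482 groups of libraries were tested for a library far from the rest, and 34 held one. Chance gives about 1 in 20, or 24.1 groups, so chance alone gives most of them, and each value is given beside the others of its group.

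Of the library measures, recovered reads were 40.5 M in WT 1w replicate D against 23.2 M to 26.1 M in the others. NPC 3w replicate C had 12003 genes with 3 or more reads against 13378 to 13605. It also had the lowest Itgam, 18335 against 47245.5 to 50372, and the highest C3ar1, 33547.5 against 18275 to 19847.

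Among the genes named throughout, Npc1 was low in WT 3w replicate D (5735 against 6897 to 7030.4) and NPC 1w replicate D (311 against 490 to 523) and high in PLX5622 replicate 1 (721 against 419 to 494). Tmem119 was low in NPC 6w replicate D (161398 against 169266 to 170320) and PLX5622 replicate 1 (67107 against 104801 to 115324), and Itgam was low in control replicate 1 (24687 against 33958.5 to 37718.5). Csf1r was low in WT 1w replicate D (363896 against 447923 to 463674), WT 6w replicate C (638110 against 746015 to 748329) and NPC 6w replicate D (553735 against 603007 to 611504).

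Of the other genes, NPC 6w replicate B was high in Serpinb1c (339 against 230.0 to 236) and Selplg (109310 against 104312 to 104779), and NPC 6w replicate D low in Mcm6 (834 against 1201 to 1257). Atp6v1a was high in NPC 1w replicate D (6661 against 5517.5 to 5611), Gfap in NPC 3w replicate B (386 against 171 to 178) and Cd63 in WT 9w replicate A (9066 against 7109 to 7432). WT 1w replicate D was high in Atp5b (31358 against 25573 to 26295) and Cox5a (3319 against 1827 to 2060). Mrc1 was low in WT 1w replicate A (3992 against 7976 to 8720) and high in WT 3w replicate C (631 against 302 to 353). H2-DMa was high in PLX5622 replicate 2 (7484 against 4390 to 5250) and Sema4b in control replicate 1 (539 against 348 to 398).

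Of the list scores, given as mean log2, WT 1w replicate A was high in homeostatic genes (15.45 against 15.19 to 15.21) and low in cell cycle genes (10.96 against 11.24 to 11.26). Control replicate 1 was low in homeostatic genes (14.45 against 14.81 to 14.91), and NPC 1w replicate A high in interferon genes (9.56 against 8.64 to 8.79). PLX5622 replicate 5 was low in inflammatory genes (9.72 against 10.34 to 10.57) and lymphocyte markers (4.39 against 4.75 to 4.86). NPC 3w replicate A was low in antigen presentation genes (10.20 against 11.37 to 11.60), WT 3w replicate B high in border-associated macrophage markers (5.08 against 4.48 to 4.56) and WT 9w replicate D low in monocyte and neutrophil markers (3.36 against 5.66 to 5.86).

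The difference between genotypes changed between ages for 457 genes in the limma interaction, with the disease-associated genes Cst7 and Axl rising more at 9 weeks.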

How the results depend on the processing

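Of 7011 values of named genes under alternatives 6527 kept their call and direction, 459 lost the call, 16 gained one and 9 turned direction. Of 1040.0 list tests 886 kept the call, 153 lost it and 1 turned. The cause of these differences was not tested. With an estimated correlation 17 of 85 list calls remained. The median, mean and test of a list differed in sign in 19 of 168 list tests, 0 of them past the threshold. The number of genes at 1 week (204) was 528 with array weights, 391 with DESeq2, 128 with all 41 libraries in one fit and 87 to 453 leaving out libraries. At 3 weeks (3777) it was 769 with only the groups compared and 2057 to 5200.0 leaving out libraries. At 6 weeks (2143) it was 872 without both NPC 6w libraries B and C, 1183 with the astrocyte score and 1524 to 3277 leaving out libraries. At 9 weeks (2665) it was 4429 with only the groups compared, 4790.0 with array weights, 1666 with the astrocyte score and 1641 to 3752 leaving out libraries. For the interaction (457) it was 891 with only the groups compared, 1130.0 with array weights, 270.0 with the replicate block, 708 with DESeq2 and 235 to 835 leaving out libraries. For PLX5622 (122) it was 79 with no filter, 435 with array weights, 416 with the replicate block, 605 with DESeq2, 534 with all 41 libraries in one fit, 214, 81 and 4 with the immediate early, Xist and monocyte covariates and 21 to 465 leaving out libraries. For control against untreated mice (0) it was 12 with no filter, 191 with array weights, 1 with DESeq2 and 0 to 7 leaving out libraries. Genes at all 4 ages (143) ranged from 69 to 277 leaving out libraries. Genes moved the same way by NPC and PLX5622 (44) were 119 with all 41 libraries in one fit and 10 to 123 leaving out libraries, and opposite genes (18) were 80 and 4 to 69. Rescaling to the same total took the share of higher genes from 53.1% to 38.1% at 3 weeks, where edgeR gave 65.5%, and from 59.1% to 48.8% at 9 weeks. Direction turned for Csf1r under PLX5622 with quantile normalization (log2 0.20) and for the cell cycle list without PLX5622 replicate 2 (adjusted p from 2.45e-06 to 0.974 leaving out libraries). For control against untreated mice it turned for Npc1 with quantile normalization (-0.0037) and DESeq2 (-0.0046), ranging from -0.23 to 0.20 leaving out libraries, and for Csf1r with quantile normalization (-0.0637), ranging from -0.0568 to 0.0827 leaving out libraries. Counts of 1 or 2 list members often moved when 1 library was left out. At 3, 6 and 9 weeks and under PLX5622 the libraries share only a letter or number. Of their pairs 1 of 4, 0 of 4, 0 of 3 and 4 of 5 correlated above 0.1 (for PLX5622 and control r from -0.148 to 0.267), and 2, 0, 2 and 0 matched best with their own. The replicate block gave 3371, 1899 and 1985 genes at 3, 6 and 9 weeks. For WT 9 weeks against 1 week 0 of 4 pairs correlated above 0.1 (r from 0.0359 to 0.0690), 3 matched best with their own, and the block by letter gave 4558 genes where the fit without it gave 4684. No paired analysis was possible for control against untreated mice, whose labels share no letter or number. Transcript length and log2 change correlated (Spearman) at 0.111, -0.118 and -0.0718 at 1, 6 and 9 weeks, -0.160 in the interaction, 0.0102 under PLX5622 and 0.0409 for control against untreated mice.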

Other observations

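Explanations for 3 patterns were weighed with tests chosen only after the results were seen, while splits of the libraries at random were set in advance.

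Splits of the libraries asked whether a random division gives as many genes. The real grouping was the only 1 of 35 splits to give its count at 1 week (204 genes, highest other 21), 3 weeks (3777, 1505), 6 weeks (2143, 8), 9 weeks (2665, 963) and for WT age (4684, 43). For the interaction 2 of 100 drawn splits gave as many (457, highest other 1251) and for PLX5622 2 of 100 (122, highest other 526), the real grouping included. In each, another split gave more genes than the real one, and no correction was made over these tests. Chance is thus unlikely here but not excluded. At 1 week the 7 other splits that part all 4 replicate pairs gave at most 0 genes. For genes at all 4 ages 1 of 100 gave as many (143, highest other 0), and for genes moved the same way by NPC and PLX5622 2 of 100 (44, highest other 144). For control against untreated mice the real count was 0, so all 56 of 56 splits had to give as many (highest other 59), and the splits say nothing about chance.

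For gene lists, chance is unlikely at 3 weeks, where 1 of 35 splits gave as many (13, highest other 11). It is also unlikely for the interaction, at 3 of 100 (15, highest other 16), with no correction over these tests. It cannot be excluded at 1 week (11 of 35 splits gave as many as 8, highest other 11), at 6 weeks (4 of 35, 13, highest other 14), at 9 weeks (14 of 35, 10, highest other 14), for WT age (3 of 35, 9, highest other 10), for PLX5622 (18 of 100, 9, highest other 15) or for control against untreated mice (14 of 56, 8, highest other 12).

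The difference between PLX5622 and control libraries could come from the state of the sorted cells, mixed sex or other blood cells. With the immediate early gene score as covariate, which 659 genes followed, the log2 changes of the called genes kept a median ratio of 0.979, and all 122 passed. Only 2.46% of the score's variance lay between the groups, which left the covariate little to remove. The ratio and the kept calls therefore do not decide about handling of the cells, and its other effects were not tested. Within libraries of female mice by Xist (3 PLX5622, 2 control) the median ratio to the change over all libraries was 0.977. Within male mice (2 and 3) it was 1.02, and all 122 genes had the same sign in both. The changes of these genes were thus present within each sex. The genes were chosen in the same libraries, which favours such ratios, so the test cannot exclude sex. With the monocyte and neutrophil score as covariate the ratio was 0.933, but 4 passed as the median SE grew 1.23-fold and 31.8% of the score's variance lay between the groups. Cells were sorted as positive for CD11b and Tmem119, a gate that should leave out monocytes and neutrophils, yet their RNA in the sort stays open.

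NPC 3w replicate C lay apart from its group, which could reflect depth, a library of another group or short transcripts. Libraries with fewer recovered reads held at least 12801 genes with 3 or more reads, against 12003 in this library of 28.6 M reads, which argues against depth. Its highest correlation with any group mean was 0.813, with its own group, which argues against another group's library. After removal of the trend with transcript length its median deviation went from 0.728 to 0.592 on the log2 scale, while the highest other library was at 0.302, so transcript length is not the whole cause. Damaged RNA could not be tested.

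Higher Gfap in NPC at 6 and 9 weeks could come from astrocyte RNA in the sorts. Gfap exceeded the rise of 11 other astrocyte markers by 2.45 ± 0.32 at 6 weeks and 3.06 ± 0.30 at 9 weeks (SE, exact permutation p = 0.0286 each, the smallest this test can give). More astrocyte RNA with an unchanged share of Gfap would not give this excess. That share was not measured, and no minimum count was asked of the other markers. The test therefore cannot exclude more astrocyte RNA as the whole cause. A lower share of microglia alone would raise the RNA of other cells alike. Gfap rose by 3.60 ± 0.94 at 6 weeks and 4.12 ± 0.45 at 9 weeks (log2, SE). Oligodendrocyte markers of at least 30 counts in WT rose by 0.63 ± 0.51 and 0.56 ± 0.23. Such neuron markers rose by 0.58 ± 0.43 and 0.74 ± 0.43. These values argue against a lower share of microglia as the whole cause. Across 17 NPC libraries of 6 and 9 weeks, deviations of Gfap and of the other markers from their group means correlated at r = 0.933 (permutation p = 1e-05, the smallest they can give), or 0.857 without the 2 farthest. Gfap thus varied together with astrocyte RNA, which the CD11b and Tmem119 gate should leave out, and Gfap per astrocyte was not measured. A lower share of microglia as part of the cause cannot be told apart, as the other astrocyte markers exceeded oligodendrocyte markers by 0.52 ± 0.29 at 6 weeks and 0.50 ± 0.13 at 9 weeks and neuron markers by 0.57 ± 0.62 and 0.32 ± 0.39 (SE).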
